A study of Mus musculus with 9 samples.

How the data were processed

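Total RNA from the quadriceps of 9 mice was hybridised to 1-colour microarrays, 1 array per mouse, after coupling of Cy3 to amplified RNA, per the labels' protocols. The scanner, the feature extraction, the normalization and any filter are not given in the sources used here. The starting point was the deposited table of processed values, with 27299 rows named by probe identifiers and 9 columns.

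The scale of the table was worked out from its values. The median of every one of the 27299 rows over the 9 arrays was 0, so the deposited values had been centred row by row and hold no level. For 20100 rows (73.6%) the differences between arrays became ratios of whole numbers, within a relative tolerance of 3e-06, once a single constant per array was taken off. After noise of up to 0.01 was added to each value, 0 rows did so. The deposited values are therefore on a log2 scale, and their sign runs from lower to higher signal. The whole numbers are taken here as array signals in scanner units. A further 1585 of the 7199 remaining rows were means of 2 log2 whole numbers.

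The array constants show what scaling the authors had applied to the log2 values. Against WT mouse 1 they were −0.23 and −0.29 for WT mice 2 and 3, 0.39, 0.01 and −0.25 for mdx mice 1 to 3, and −0.61, −1.09 and −1.05 for treated mice 1 to 3. The 75th percentile of the recovered signal moved the opposite way by a similar amount, such as 1.19 and 1.16 for treated mice 2 and 3, except in mdx mouse 2, where both shifts were small (0.01 and 0.04). Medians of the deposited values were not aligned. They were 0.10, 0.00 and 0.10 in WT mice 1 to 3, 0.33, 0.26 and −0.07 in mdx mice 1 to 3, and −0.39, −0.17 and −0.32 in treated mice 1 to 3. The values were used as deposited because a constant per array had already been applied, although the condition set for this, aligned arrays, was met only in part. Other scalings were run as alternatives. Whether the constants came from a percentile of each array or from another rule is not given in the sources used here.

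The platform annotation gave 1 gene symbol for 21877 rows, several for 0 rows and none for 5366 rows. A further 56 rows had control identifiers and were left out, so 27243 rows were tested. Symbols were compared with a RefSeq gene table of assembly GRCm38.p6 through their Entrez identifiers, and 0 symbols changed. Whether the identifiers belong to the values was tested with 446 pairs of rows listed under the same gene, with the recovered signal levels, and with 31 gene lists and cell type lists of 621 genes, 580 of them measured. Random pairs and lists served as background (1000 sets of pairs, 1000 lists for correlation and 10000 lists for signal). Because identifiers and values were found not to go together, rows served as the features, the choice fixed for unnamed probes. Gene symbols appear only as the symbol a row is listed under. The planned selection of 12 rises and 12 falls by gene name was replaced by at most 2 identifiers in each direction, those with the largest change among rows past the threshold whose groups do not overlap.

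Groups were taken from the sample titles. The 3 contrasts were fitted to all 9 arrays with limma (lmFit and eBayes, group means, 1 shared estimate of spread), two-sided, and a row was called at a Benjamini-Hochberg adjusted p under 0.05. The gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists, the tests, the contrasts and most alternatives were fixed before the data were examined. The movement of mdx-changed rows in treated mice was cross-fitted. Each mdx mouse was left out in turn, rows were called without it, and the mean of the treated mice minus the left-out mouse was regressed through 0 on the mdx minus WT difference of the others. A slope of −1 would be a full return to WT and 0 no movement.

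Rows with a geometric mean signal of at least 100 units over the 9 arrays (5612 rows) were examined on their own, a limit chosen after seeing the data. With 3 mice per group the number of arrays limits the precision. On simulated data with the spread of each row, the fit of 27243 rows recovered 57% of rows changed by 2 on the log2 scale and 1% of rows changed by 1 for mdx against WT, with 3 false calls. For treated mdx against mdx the shares were 70% and 2%, with 2 false calls, and for treated mdx against WT 70% and 1%, with 4. The simulation changed 100 rows by each size, with noise independent between rows and the same spread in every group. In the real arrays dim rows shifted together. The simulated shares and false calls therefore do not give those of the real fits. The titles number the mice within each group. Of 9 pairs of arrays with the same number in different groups, 2 had deviations from the group means that correlated above 0.1, so the numbers were not used to pair mice. Alternatives covered the scaling, the samples in the fit, the variance model, array weights, the mouse number as a block, the size of change, the signal limit and leaving out each mouse.

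Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.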

Results

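Transcript levels were measured in the quadriceps of 3 wild-type C57BL/6J mice (WT), 3 untreated mdx mice and 3 mdx mice given tadalafil. The mdx mouse carries a mutation in Dmd, the dystrophin gene, and is a model of Duchenne muscular dystrophy. Tadalafil inhibits the cGMP-degrading phosphodiesterase encoded by Pde5a. It was given in the drinking water at 30 mg/kg per day from before birth for 4 months, up to 16 weeks of age. The comparisons ask what differs in dystrophic muscle, what differs under the drug, and what remains different from healthy muscle. The 9 arrays are from separately numbered mice. The median recovered signal ran from 15 to 31 units per array and the 75th percentile from 84 to 238, so most rows were dim.

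The 3 healthy muscles resembled each other more closely than the dystrophic ones did. Over 5624 rows with a geometric mean of at least 100 signal units, control rows included, log2 signals of WT arrays correlated at 0.973 to 0.983 across rows. Between mdx arrays the correlation was 0.889 to 0.949, and between treated arrays 0.941 to 0.955. WT and mdx arrays correlated at 0.889 on average, WT and treated arrays at 0.878, and mdx and treated arrays at 0.899. Mdx mouse 3 correlated at 0.935, 0.938 and 0.917 with treated mice 1 to 3, and at 0.912 and 0.949 with mdx mice 1 and 2. In the deposited values of all rows it correlated at 0.315, 0.0487 and 0.247 with treated mice 1 to 3. With mdx mice 1 and 2 it correlated there at 0.176 and 0.186. Rows are not independent replicates, and these values describe the 9 arrays.

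The gene names listed for the rows did not go with the values beside them. In 446 pairs of rows listed under the same gene, the median correlation of the values over the 9 arrays was −0.0525, against 0.00314 for random pairs (95% of random sets between −0.0659 and 0.0722). The log2 signal of 245 such pairs correlated at −0.0911, within the range of random pairs (−0.124 to 0.125). Rows listed under olfactory and vomeronasal receptors, which muscle hardly uses, had a median signal of 21.7 units, rows listed under ribosomal protein genes, among the most abundant transcripts of any cell, 24.9 units, and all rows 19.5 units. The row listed under Acta1, the skeletal muscle actin, read 4 to 35 units, the row listed under Ckm, the muscle creatine kinase, 7 to 23, and the row listed under Ttn, the giant sarcomere protein titin, 2 to 13. The row listed under Mylpf, a fast myosin light chain, read 2485 to 7408 and the row listed under Myh4, a fast myosin heavy chain, 1512 to 2580. Of 31 gene and cell type lists, 2 had a within-list correlation above the 95th percentile of random lists (complement, 0.270, and neutrophil and mast cell markers, 0.223), and of 30 lists 1 had a median signal above it (interferon response, 492 units). Changes are therefore given by row and not by gene.

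**Figure D1:**
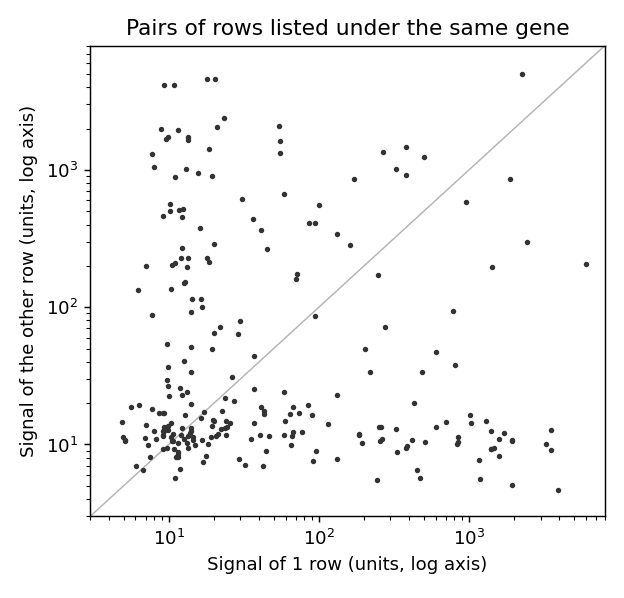
Recovered signal, in units on log axes, of the 2 rows of each of 245 pairs listed under the same gene, as geometric means over 9 arrays, with the line of equal signal in grey. Points do not follow the line, and the log2 signals correlated at −0.0911.

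Between mdx and WT muscle, 183 of 27243 rows passed the threshold, 120 of them higher and 63 lower in mdx. Their median absolute difference was 2.00 on the log2 scale. The largest rises were in row A_51_P245503, from −2.98 ± 0.30 in WT to 3.10 ± 0.99 in mdx (mean ± SD of centred log2 values, n = 3 each; difference 6.08 ± 0.49 SE, limma adjusted p = 0.00225), and in row A_51_P510663, with a difference of 5.71 ± 0.61 and an adjusted p of 0.00651 in limma. Row A_55_P2044602 fell from 5.09 ± 0.73 in WT to −0.08 ± 0.12 in mdx (difference −5.16 ± 0.36 SE, limma adjusted p = 0.00155). Row A_51_P156158 had a difference of −5.14 ± 0.45 with an adjusted p of 0.00329 in limma. Both falls missed the threshold with a variance trend and robust fitting (limma adjusted p = 0.376 and 0.320) and passed in the other 20 of 21 and 17 of 18 alternatives, while the rises passed in all 16 and 21 alternatives run on them. Adjusted p lay between 6.39e-05 and 0.376 for the first fall and between 0.00118 and 0.320 for the second. In treated mice these rows had means of −0.06, −0.18, −0.18 and −0.37. The signal level of row A_51_P245503 was not recovered, so its WT values were not shown to lie above background. The values of the 2 groups did not overlap in any of the 183 rows, nor in 28.2% of all rows, where chance gives 10% on average. Rows share shifts of whole arrays, so the share over all rows is no test of a difference between the groups. Rows called at such large differences would seldom overlap, so their separation adds little. Calls were 149 higher and 163 lower with each array centred on its median, and 929 and 768 after quantile normalization between arrays. The count was 34, 29 and 56 without WT mice 1, 2 and 3, 427 and 92 without mdx mice 2 and 3, and 111 without treated mouse 3.

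Between treated and untreated mdx muscle, 4606 rows passed, 335 higher and 4271 lower in treated mice, and the median over all 27243 rows was −0.53. The lower calls lay mostly in dim rows. Of 11843 rows under 32 signal units, 2812 were lower and 1 was higher. Of 5612 rows with at least 100 units, 283 were lower and 185 higher, and their median was −0.10. Fitted on their own, these rows gave 557 calls, 352 of them lower, but 1 call and 0 lower without treated mouse 3, 104 without WT mouse 1 and 861 without mdx mouse 3. The median of the deposited values in the 8605 rows under 16 units was −1.06, −0.31 and −0.68 in treated mice 1 to 3 and 0.81, 0.59 and −0.22 in mdx mice 1 to 3. Row A_55_P1984198 had the largest rise, from −2.89 ± 0.77 to 1.02 ± 0.92 (SD, n = 3 each; difference 3.91 ± 1.09 SE, limma adjusted p = 0.0441), and passed in 6 of 16 alternatives. Its signal level was not recovered, as for rows A_51_P245503 and A_55_P2119721. These rows were therefore not shown to lie above background, and the sizes of their differences are uncertain. The rows with the 2 largest falls read 10.6 and 6.32 units and were not shown to lie above background, so their falls are not given. With each array centred on its median 642 rows were higher and 602 lower, and after quantile normalization 194 and 59. These scalings give the arrays a common median or distribution, so the balance after them does not show where the excess of lower calls came from. The 20064 rows with a recovered signal gave 200 higher and 2725 lower calls as deposited, and 2 and 0 after quantile normalization of the signals, but with at least 100 units such signals still gave 206 higher and 265 lower. The count was 0 without mdx mouse 1 (8005 rows at an unadjusted p under 0.05 in limma), 7 without mdx mouse 2, 10500 without mdx mouse 3, 740 and 1 without treated mice 1 and 3, and 1240, 2468 and 2135 without WT mice 1 to 3. With only these 6 mice in limma's fit, 0 rows passed (8487 at an unadjusted p under 0.05).

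**Figure D2:**
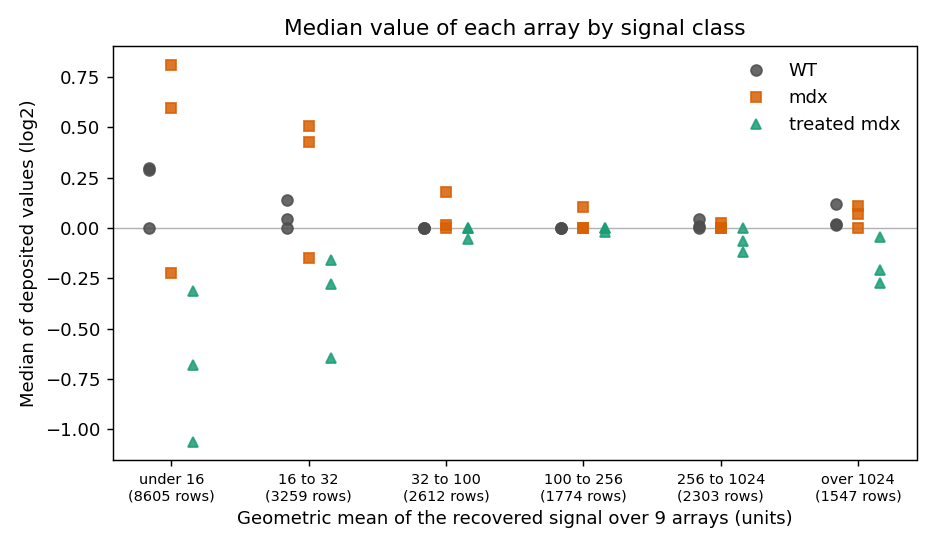
Median of the deposited log2 values of each array (1 point per mouse, 3 per group) for rows grouped by the geometric mean of their recovered signal in units. Treated arrays lie at −0.31 to −1.06 in rows under 16 units, and at −0.27 or nearer to 0 in every class of at least 32 units.

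**Figure D3:**
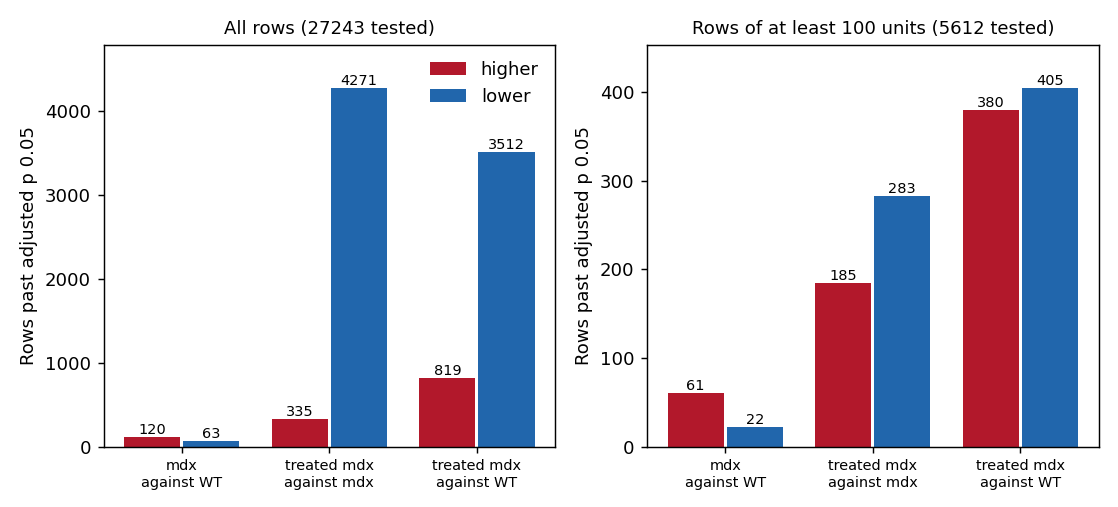
Number of rows higher (red) and lower (blue) at a limma adjusted p under 0.05 in each comparison, for all 27243 rows and for the 5612 of them with at least 100 signal units, both from the fit of all rows. For treated against untreated mdx, 4271 of 4606 calls are lower in the left panel and 283 of 468 in the right.

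Between treated mdx and WT muscle, 4331 rows passed, 819 higher and 3512 lower in treated mice, with a median of −0.52 over all rows. In the rows of at least 100 units 380 were higher and 405 lower. The largest rise was in row A_55_P2119721, from −5.35 ± 0.48 in WT to 1.70 ± 1.09 in treated mice (SD, n = 3 each; difference 7.05 ± 0.53 SE, limma adjusted p = 0.000954). The signal level of row A_55_P2119721 was not recovered, so its WT values were not shown to lie above background. The largest fall was in row A_51_P300532, at 189 signal units, from 4.41 ± 0.12 to −1.32 ± 0.40 (difference −5.73 ± 0.30 SE, limma adjusted p = 0.000222), and in untreated mdx this row was at 0.13 ± 0.51. After centring each array on its median 1516 rows were higher and 1289 lower, after quantile normalization 2447 and 1132. Without WT mice 1, 2 and 3 the count was 615, 397 and 675, without treated mice 1 and 3 it was 2217 and 1441, and without mdx mouse 3 it was 6744.

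Whether rows that differed between mdx and WT moved toward WT under tadalafil depended on the mdx mouse left out. With mdx mouse 1 left out, 126 rows were called from the other mice, and the treated mice differed from mouse 1 by −0.0328 of the mdx minus WT difference. The fraction was 0.140 over 427 rows with mdx mouse 2 left out and −0.202 over 92 rows with mdx mouse 3 left out, a mean of −0.0317 ± 0.171 (SD over the 3 left-out mice). In these 3 sets the median shift from the left-out mouse to the treated mice was −0.39, −0.03 and −0.51 in rows higher in mdx and −0.42, −0.73 and 0.22 in rows lower in mdx, beside −0.74, −0.67 and −0.24 over all rows, so the fractions mix the general fall in treated arrays with any movement toward WT. In rows of at least 100 units the mean fraction was −0.0647 ± 0.126, and the shifts over all these rows were −0.18, −0.15 and −0.07. The fold changes of mdx against WT and of treated against untreated mdx correlated at −0.327 across rows, and unchanged groups simulated row by row with the same shared mdx arrays gave −0.499 (−0.525 to −0.478 in 100 draws). The covariance was −0.168, against −0.0806 in the simulation, and in rows of at least 100 units −0.0956 against −0.0375. The correlation lay nearer to 0 than in the simulation. The simulation gave a row the same spread in every group, whereas limma's array weights were lower for every mdx mouse than for every WT mouse. A larger spread among mdx mice would alone bring the covariance further below 0. The gap between the covariance and its simulated value therefore cannot show a move toward WT. With no array shared between the 2 differences, the covariance was −0.0739 ± 0.0716 over all rows (SD over the 3 left-out mdx mice). It was below 0 for each mouse, the side of a move toward WT. In rows of at least 100 units it was −0.0205 ± 0.0591, with 0.0343 for mdx mouse 2. This check was chosen after seeing the data. Rows under 32 units had a median of 0.14 for mdx minus WT and −1.06 for treated minus mdx. In rows of at least 100 units the medians were −0.04 and −0.10. This contrast of dim and bright rows would by itself pull the covariance over all rows below 0. The check therefore cannot show a move toward WT either.

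The genes and lists fixed in advance gave no call that could be read by name. The row listed under Dmd differed by 0.53 ± 0.31 between mdx and WT (SE, limma adjusted p = 0.369) and the row listed under Pde5a by 0.24 ± 0.22 between treated and untreated mdx (SE, limma adjusted p = 0.438). For the row listed under Nos1, the neuronal nitric oxide synthase, the difference between mdx and WT was −0.44 ± 0.56 (SE, limma adjusted p = 0.702). For the row listed under Utrn, the dystrophin homologue utrophin, it was −3.00 ± 2.45 (SE, limma adjusted p = 0.525), with an SD of 6.16 among the WT mice. Without WT mouse 1 that difference was 0.56 (limma adjusted p = 0.736), so its sign rested on 1 array, and adjusted p lay between 0.382 and 0.736 over all alternatives. By limma's camera 0 of 31 lists passed in each of the 3 comparisons, and 0 had an unadjusted p under 0.05. With an estimated correlation 0 passed as well. By fry, which asks whether the rows of a list move one way and does not set them against other rows, 0 lists passed for mdx against WT, 24 for treated against untreated mdx and 21 for treated mdx against WT. Of 588 list rows, 0.680% were called for mdx against WT, 17.7% for treated against untreated mdx and 15.8% for treated mdx against WT. Of all rows 0.672%, 16.9% and 15.9% were called. Adjusted over the list alone, 28, 136 and 106 list rows passed in the 3 comparisons.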

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

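The settings with recovered signals, a limit of 100 signal units or control rows kept were chosen after seeing the data, and the cause of each shift was not tested unless stated. With 3 mice per group and most rows dim, counts depended on nearly every choice, and dim rows carried most of the calls between treated and untreated mdx. Counts are given in the order mdx against WT, treated against untreated mdx, treated mdx against WT, beside 183, 4606 and 4331. Centring each array on its median gave 312, 1244 and 2805 calls. Quantile normalization between arrays gave 1697 and 253, with 3579 in the last. The 20064 rows with a recovered signal gave 104, 2925 and 2511 as deposited, and 1858, 2 and 1048 after quantile normalization of those signals, a step that also takes off the array constants. Array weights gave 1310, 7209 and 12019. A variance trend with robust fitting gave 26 in the first. Only the compared groups in the fit gave 0 and 7664 in the last 2. Rows of at least 100 units, fewer tests over less noisy rows, gave 505, 557 and 1374, the same rows centred on their medians 506, 478 and 1254, and with quantile-normalized recovered signals 436, 471 and 1153. Leaving out 1 mouse gave 29 to 427, 0 to 10500 and 397 to 6744 calls, and in rows of at least 100 units 125 to 898, 1 to 861 and 474 to 2123. The lowest of those for treated against untreated mdx came without treated mouse 3. With the mouse number as a replicate block the counts were 69, 2112 and 3687. Same-numbered arrays had deviations correlating between −0.179 and 0.152, so the mice share only a number. All 4606 calls between treated and untreated mdx and all 183 and 4331 others exceeded 1.5-fold, and control rows changed the counts by little (183, 4608 and 4348). The list tests stayed at 0 with camera under each of these settings, and fry gave 24 and 21 lists. Because names did not go with the values, these tests cannot speak for or against a change of the listed pathways. The mean fraction for mdx-changed rows lay between −0.180 and 0.0810 and took both signs. For the 2 largest rises and 2 largest falls of each comparison and the rows listed under Dmd, Utrn, Nos1 and Pde5a, 382 of the values under alternatives kept their side of the threshold, 38 lost it, 1 gained it and none past the threshold changed sign. The rows listed under these symbols had not passed, so they kept their side by not passing again. Most losses lay in treated against untreated mdx. There, row A_51_P143721 lost the threshold in 5 of 18 alternatives and A_51_P418809 in 12 of 18. Row A_55_P1984198 lost it in 10 of 16 and A_55_P1995477 in 9 of 16. Not run were the filter on the lowest 30% by mean, since centred rows hold no level, the mean of a gene's probes, since names were not borne out, the floor for linear values, and array weights, block and compared groups alone for the mean fraction. Without WT mouse 1 or 2 too few rows were called to give that fraction.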

Other observations

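All tests of explanations in this part, and the share that follows, were chosen after the results had been seen. The share is the slope of the treated minus WT difference on the mdx minus WT difference across rows. It was 0.936 ± 0.238 (SD over 3 treated mice) over the 5612 rows of at least 100 signal units. As a covariance over a variance it can exceed 1 and is not the fraction of the mdx difference that remained. It was computed from covariances in which the mdx and the treated difference were taken against different WT mice, so that no array enters both sides of a covariance, and on simulated data with a share of 0.5 the method returned 0.499. The single treated mice gave 0.693 to 1.17, and leaving out any 1 of the 9 mice gave 0.819 to 1.06. Over all 27243 rows the share was 0.778. Corrected for noise, the 2 differences correlated at 0.793, and the variance of the difference from WT was 0.320 for mdx and 0.447 for treated mice.

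The differences of the 2 mdx groups from WT were partly shared. A constant per array drops out of covariances across rows, so the share could not test scaling of that kind. With quantile-normalized recovered signals, which have a common distribution, the share was 0.929. This argues only against differences in the distribution of signals between arrays as the cause of the shared part. The shared part, with a slope of 0.936, could come from the dystrophin mutation, from another strain background of the mdx mice, which the labels do not give, or from arrays of WT mice run apart from the others. These cannot be told apart, because each would set WT against both mdx groups.

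Identifiers and values did not go together. Arrays without reproducible signal are argued against by the WT arrays, whose lowest correlation was 0.973 in rows of at least 100 units. A shift or reversal of the whole list of identifiers in its given order is argued against too, since the highest correlation of signal in same-gene pairs over 54598 such orderings was 0.277 and 10 re-paired sets gave 0.251 to 0.318. Identifiers standing beside the values of other rows may account for the pattern. The correlation of −0.0911 in the given order is part of the pattern itself, so it is no separate test of this. Whether the table or the annotation of the platform is at fault stays open, and no biological explanation was tested.

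Lower rows prevailed in treated against untreated mdx. A fall of the same size in all rows was tested by the median of rows under 32 units minus that of rows of at least 100, which differed by −0.845 between treated and mdx mice (treated minus mdx, pooled SD 0.429 between arrays). It stays open, because mdx mouse 3 at −0.187 lay below treated mouse 2 at −0.138 and the exact permutation p was 0.20, where 3 arrays against 3 allow 0.10 at best (two-sided). The scaling and background of dim rows and an effect of the drug on transcripts of low level cannot be told apart. Either would leave fewer lower calls among bright rows. In rows of at least 100 units 60.5% of calls were lower, against 92.7% over all rows, and the limit was set after seeing this. The 1547 brightest rows with a recovered signal were slightly lower in treated mice too. Their deposited medians were −0.04, −0.21 and −0.27 in treated mice 1 to 3. In mdx mice 1 to 3 they were 0.11, 0.07 and 0.00, and in WT mice 0.01, 0.02 and 0.12. Neither explanation of dim rows covers this smaller fall, and its cause was not tested. The 25th percentile of the recovered signal was 7, 18 and 13 units in treated mice 1 to 3. It was 13, 15 and 10 in mdx mice and 13, 14 and 15 in WT mice. Before the array constants it thus lay below every WT and mdx array only in treated mouse 1. The deposited values also hold the constants, −0.61, −1.09 and −1.05 in treated mice 1 to 3. The number of calls among bright rows varied with the mouse left out. The fit of rows of at least 100 units gave 1 call without treated mouse 3 and 861 without mdx mouse 3. Leaving out a mouse also leaves fewer arrays to estimate the spread, so these counts do not show on which arrays the differences rest.

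Each of the 3 comparisons sets 3 mice against 3, which allows 10 splits of the 6 mice, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many rows. The real splits gave 183, 4606 and 4331 rows over all rows and 505, 557 and 1374 in the fit of rows of at least 100 units, and the highest of the other splits gave 0 in each. Every other split puts mice of both real groups on each side. Any difference between the real groups, whatever its cause, then adds to the spread and lowers the count. The contrast with 0 is therefore no separate support for the calls.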
